A study of Mus musculus with 12 samples.

How the data were processed

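Gene-level read counts and TPM values from total RNA of 12 mouse embryonic fibroblast libraries were used. Per the submitters' notes, reads per gene were counted with featureCounts 1.5.2 on the mm10 build. The sources used here give no aligner or strand setting, so reads of overlapping or antisense genes cannot be separated. The deposited counts are whole numbers that are not normalized. The deposited TPM values were made by the authors from the same counts, as each count over the gene's length rescaled to the same total in each library, which was checked on the tables. The tables list 32168 genes, each with at least 1 read in at least 1 of the 12 libraries. All 32168 gene IDs matched the reference table of gene names, 0 columns lacked a sample, and coordinates are those of the deposited tables on mm10.

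Groups were taken from the sample titles: 8 groups of genotype, treatment and day, with 2 repeats in each CP1 group and 1 library in each DMSO group. Descriptions of the WT DMSO libraries carry no day, so their day rests on titles and column names. Library totals ran from 16970834 to 25299262 counts, between which a gene at 1 CPM has about 17 to 25 reads, so that depth limited mainly genes below that level. The 2 WT DMSO libraries differed by a chi-square per degree of freedom of 1.95 over genes with at least 20 reads, above sampling noise, and were kept as separate samples.

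Counts were normalized by TMM and tested with the quasi-likelihood F-test of edgeR 4.0.16 (robust fit) under R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Genes were kept by edgeR's filter on genotype and treatment (minimum count 10, minimum total 15), which left 16595 genes and removed 15573. Comparisons of genotype and treatment used a model with 4 means and a day term per genotype (6 coefficients, 6 residual degrees of freedom). Its common biological coefficient of variation was 0.098. The day term is assumed equal under DMSO and CP1, although WT day calls numbered 0 and 2532 in these. Comparisons at each day or between days used 8 group means (4 residual degrees of freedom, coefficient 0.051). There a lone DMSO library is assumed to vary like the other groups. For the other comparisons 8 means gained 10 calls of named genes and lost 2. CPM values are counts over TMM-scaled library totals, given as mean ± SD with n libraries.

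Named genes were those of a fixed set (Lats1, Lats2, Yap1, Wwtr1, Tead1 to Tead4, Ccn1, Ccn2, Ankrd1, Amotl2, Axl). To these came the 8 higher and 8 lower genes with the largest log2 fold change among called genes with mean log2 CPM of at least 2 and no overlap between the sides (5 and 5 for other comparisons), and up to 3 called members per list with the smallest p. For the difference of CP1 effects the condition on overlap was left out, and predicted gene models without a proper symbol were passed over. A gene that the rule selects is not reported here. Genes and values singled out beyond that rule were chosen after their values were seen: Col3a1, Xist, Thy1, Pdgfd and the HOX genes in single libraries and the macrophage transcripts Lyz2, Csf1r and Cd68. Design, tests, gene lists, the rule for names and the settings described later as chosen beforehand were set before the data were examined.

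The 32 gene lists held 678 symbols, of which 664 matched the table. They covered YAP/TAZ-TEAD targets, Hippo components, Wnt targets, G1/S, G2/M, matrix, contractile and SRF targets, TGF-beta targets, cholesterol synthesis, fatty acid synthesis, integrated stress response, unfolded protein response, p53 targets, interferon-stimulated genes, NF-kB targets, NRF2 targets, aryl hydrocarbon receptor targets, hypoxia and glycolysis, nuclear-encoded respiratory chain, mitochondrially encoded genes, immediate early genes, HOX genes and sex-linked genes. Cell type lists covered adipocytes, cartilage and bone, skeletal muscle, fibroblasts, macrophages, endothelium, epithelium, neural and erythroid cells. Lists with at least 5 tested genes (30 lists) were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. Calls among list members are given over all genes and adjusted over the list alone.

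For genes at 0 counts in a group, fold changes are bounds against a floor of 3 counts over that group, and with 1 to 3 counts the ratio has a 95% exact binomial interval. The relation between CP1 and genotype effects used disjoint libraries of different days, and its value with shared DMSO libraries was set beside 10 simulations of unchanged groups. Every count pipeline was first tested on simulated data with 200 genes changed. For CP1 in WT cells edgeR recovered 62.1%, 67.2% and 89.2% of genes changed 1.5-, 2- and 4-fold (16018 genes tested), for the genotype comparison in DMSO 27.7%, 74.2% and 81% (15970 genes), for CP1 in DKO cells 62.5%, 68.2% and 81.2% (15977 genes), and for the difference of effects 18.2%, 63.9% and 78.5% (15959 genes).

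Other settings chosen beforehand were a fold threshold of 2, DESeq2's size factors, no low-count filter, a stricter filter (1 CPM in 4 libraries), the DESeq2 1.42.0 Wald test, limma on log2(TPM + 1) with pseudocount 1, other designs, fewer libraries in the fit, a replicate block, and leaving out each library. A fold change on the log2(TPM + 1) scale understates the change of low genes. After the data were seen, a fit without the 3 WT CP1 libraries with over 1% of counts in ribosomal RNA genes was added, with TPM rescaled without rRNA and miRNA genes. In those libraries the ribosomal RNA gene model Gm23935 alone held 20.4% to 21.9% of TPM, against 0.1% in the other WT libraries, so TPM of all other genes was lower there.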

Results

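RNA-seq read counts per gene were analysed for 12 libraries of mouse embryonic fibroblasts, connective-tissue cells cultured from embryos. The cells were wild type (WT) or lacked the kinases LATS1 and LATS2 (DKO). These Hippo-pathway kinases phosphorylate and restrain the co-activators YAP and TAZ, partners of the TEAD DNA-binding proteins. Cells received MGH-CP1 (CP1), an inhibitor of TEAD palmitoylation, at 1 µM, or its solvent DMSO, for 2 or 4 days. Each genotype had 2 CP1 libraries and 1 DMSO library per day, so 4 CP1 and 2 DMSO libraries. Tests covered 16595 genes. The labels do not state whether repeats came from separate cultures, so every p-value measures only the spread between these samples, which may be technical. The 2 DMSO libraries of a genotype differ in day and were averaged with a day term. The number of embryos or cultures behind each genotype is also not stated.

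Lats1 (ENSMUSG00000040021.13, mm10 chromosome 10, 7681214 to 7716460, plus strand) and Lats2 (ENSMUSG00000021959.16, chromosome 14, 57689662 to 57758388, minus strand) were low in every library labelled DKO. Lats1 stood at 14.3% of the WT DMSO mean in DKO DMSO at 2 days and 22.1% at 4 days, and at 34.2%, 31.2%, 35.6% and 34.9% in the 4 DKO CP1 libraries. Lats2 stood at 28.4% and 28.3% in DKO DMSO and at 26.3%, 27.5%, 31.1% and 30.9% in DKO CP1. In WT CP1 libraries Lats1 stood at 82.5%, 83.5%, 92.6% and 94.1% and Lats2 at 76.9%, 85.3%, 87% and 84%, while the WT DMSO libraries held 102.5% and 97.5% of the mean for Lats1 and 104.4% and 95.6% for Lats2. Counts per gene can hold reads from exons that a deletion leaves in place, so a residual level does not measure intact transcript.

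Other genes followed closely lie as follows on mm10. Yap1 (ENSMUSG00000053110.13) lies on chromosome 9 at 7931999 to 8004596 and Wwtr1 (ENSMUSG00000027803.14) on chromosome 3 at 57455649 to 57575910, both on the minus strand. Ccn1 (ENSMUSG00000028195.4) spans 145646976 to 145649981 of chromosome 3, minus strand. Ccn2 (ENSMUSG00000019997.11) spans 24595442 to 24598683 of chromosome 10, plus strand. Ankrd1 (ENSMUSG00000024803.9) spans 36111961 to 36120099 of chromosome 19, minus strand. Amotl2 (ENSMUSG00000032531.15) spans 102716672 to 102733418 of chromosome 9, plus strand. Col3a1 (ENSMUSG00000026043.18) spans 45311538 to 45349706 of chromosome 1 and Dcn (ENSMUSG00000019929.16) 97479609 to 97518143 of chromosome 10, both plus strand. Thy1 (ENSMUSG00000032011.5) spans 44043384 to 44048579 and Pdgfd (ENSMUSG00000032006.15) 6168584 to 6378850 of chromosome 9, both plus strand. Hoxd11 (ENSMUSG00000042499.13) spans 74679557 to 74687016 of chromosome 2, plus strand. Xist (ENSMUSG00000086503.4) spans 103460366 to 103483254 of chromosome X, minus strand.

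**Figure D1:**
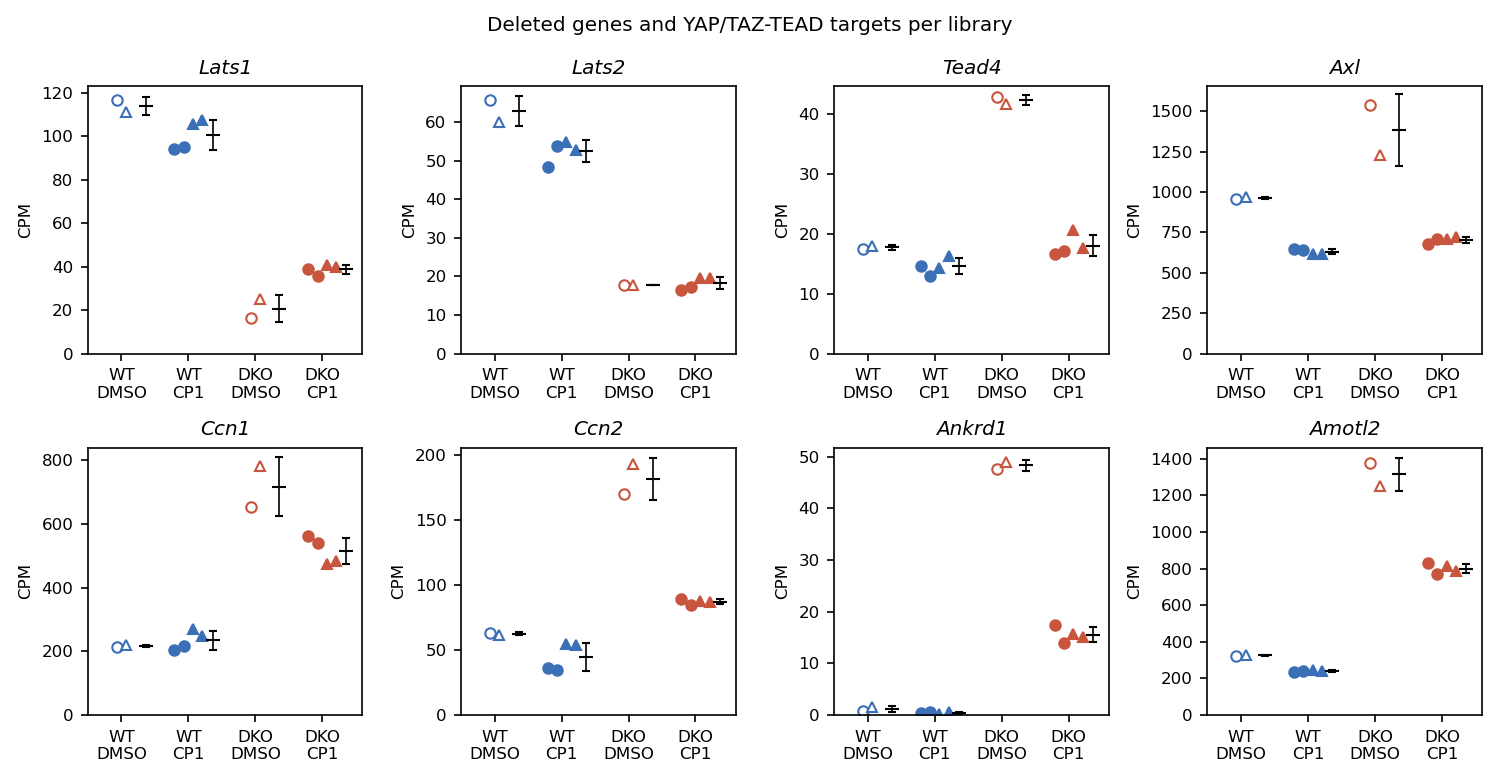
CPM of 8 genes in each of the 12 libraries (blue, WT; red, DKO; open symbols, DMSO; filled symbols, CP1; circles, 2 days; triangles, 4 days; bars, mean ± SD of the genotype and treatment). Ankrd1 stood at 1.23 in WT DMSO, 48.32 in DKO DMSO and 15.53 in DKO CP1, and Lats2 fell from 62.92 in WT DMSO to 17.85 in DKO DMSO.

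The first comparison asked how DKO and WT cells differed in expression without drug. Loss of the LATS kinases cannot be told apart here from another origin of the DKO cells, since the labels give no line per genotype. Of 21 YAP/TAZ-TEAD target genes 15 were higher and 1 lower in DKO than in WT cells in DMSO. The list did not hold with an estimated correlation (camera adjusted p = 0.111). That correlation was −0.00851, below the preset 0.01, so correlated members do not explain the loss. By fry, which does not compare a list with other genes, the list was higher (adjusted p = 5.62e-07). Ankrd1, a nuclear ankyrin-repeat cofactor, stood at 48.32 ± 1.02 CPM (counts scaled to the library total; SD, n = 2) against 1.23 ± 0.56 (n = 2). Its log2 fold change was 5.51 (SE 0.29; adjusted p = 5.93e-09, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, as for all gene p-values here). The matricellular protein gene Ccn1 was higher by 1.85 (SE 0.14; edgeR adjusted p = 1.11e-07) and its relative Ccn2 by 1.69 (SE 0.15; edgeR adjusted p = 6.9e-07). The angiomotin-family gene Amotl2 was higher by 2.05 (SE 0.10; edgeR adjusted p = 1.89e-09) and Tead4 by 1.26 (SE 0.13; edgeR adjusted p = 2.71e-06). The receptor tyrosine kinase gene Axl was higher by 0.54 (SE 0.11; edgeR adjusted p = 0.00111). Yap1 (log2 fold change −0.10), Wwtr1, which encodes TAZ (0.15), Tead1 (0.27) and Tead3 (0.07) did not pass. Without the DKO DMSO 2-day library these 4 genes passed, with log2 fold changes of −0.51, 0.27, 0.66 and 0.30. Tead2 was higher by 0.42 (SE 0.12; edgeR adjusted p = 0.00569). That call was lost without the WT DMSO 2-day library (0.25, adjusted p = 0.183) or the DKO DMSO 2-day library (0.19, adjusted p = 0.113). Lats1 and Lats2 were lower by log2 fold changes of −2.57 (SE 0.14; edgeR adjusted p = 8.47e-09) and −1.88 (SE 0.11; edgeR adjusted p = 1.6e-08).

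Of the genes chosen by size, each had every library of one genotype above every library of the other. The ligand gene Wnt7b had 1081 counts in DKO DMSO and 1 in WT DMSO, a ratio of 1285 (95% interval 230.1 to 50800). Without the WT DMSO 2-day library edgeR no longer called it, although the fitted log2 fold change was 8.69 against 9.38 with all libraries. Wnt7a was higher by 9.07 on the log2 scale (SE 0.41). The desmosomal plaque gene Pkp1 was higher by 7.86 (SE 0.17; edgeR adjusted p = 3.78e-12), at 126 ± 25.8 against 0.71 ± 0.04 CPM (n = 2 each). The retinaldehyde dehydrogenase gene Aldh1a1 and its relative Aldh1a7 were higher by 7.92 (SE 0.73) and 8.80 (SE 0.40). The endocytic receptor gene Lrp2 was higher by 7.30 (SE 0.36) and the lectin gene Siglecg by 6.02 (SE 0.22). The homeobox gene Tlx2 had 561 against 3 counts, a ratio of 222 (95% interval 75.7 to 1081). Several genes had no count in either DKO DMSO library. Among them the fibroblast surface antigen Thy1 was at least 1369-fold lower, the guanine deaminase gene Gda at least 918-fold and the interferon-induced gene Ifi44l at least 630-fold. The growth factor gene Pdgfd was at least 506-fold, the class I histocompatibility gene H2-T10 at least 395-fold, the homeobox gene Hoxd11 at least 358-fold and Prr16 at least 325-fold lower. Without the DKO DMSO 2-day library edgeR no longer called Pdgfd, Ifi44l and Hoxd11. Fitted log2 fold changes were then −12.97, −9.42 and −12.44 against −12.95, −12.52 and −12.42 with all libraries. Pdgfd and Hoxd11 had 0 counts in every DKO library, so their lost calls do not reflect a smaller difference. These bounds and intervals, like those given later, cover counting error only. The lipocalin gene Apod stood at 0.23 ± 0.08 against 522 ± 31.5 CPM (n = 2 each), a log2 fold change of −12.80 (SE 1.25).

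Of the gene lists, 12 of 30 passed camera's test in this comparison, and only the nuclear-encoded respiratory chain list held with an estimated correlation. Of the 21 tested YAP/TAZ-TEAD targets, 15 were higher and 1 lower over all genes tested, and 16 and 2 when adjusted over the list alone. By TPM 12 were higher and 4 lower, and 4 were lower without the DKO DMSO 2-day library. The list's median log2 fold change was 0.97 (camera adjusted p = 0.00147, adjusted p = 0.111 with an estimated correlation). All 30 interferon-stimulated genes were lower, over all genes and adjusted over the list alone, and 25 without the DKO DMSO 2-day library. Their median was −6.64 (camera adjusted p = 2.31e-13, adjusted p = 0.342 with an estimated correlation), and the antiviral ADP-ribosyltransferase gene Parp14 stood at 3.3 ± 0.88 against 492 CPM (n = 2 each). Of 33 collagen and matrix genes 25 were lower and 5 higher, the same when adjusted over the list alone, and 2 were higher without the WT DMSO 2-day library or by TPM. The matrix median was −1.41 (camera adjusted p = 2.4e-05, adjusted p = 0.342 with an estimated correlation). The proteoglycan gene Dcn had a log2 fold change of −10.00 (SE 0.16; edgeR adjusted p = 3.83e-13), and the matrix genes Thbs2 and Fbln1 had −6.13 (SE 0.17) and −5.09 (SE 0.15). Of 17 fibroblast markers 15 were lower and 1 higher, the same adjusted over the list alone, including Ly6a (−3.92), the limb homeobox gene Prrx1 (−2.33) and Tbx5 (−5.00). Their median was −3.92 (camera adjusted p = 1.83e-05, adjusted p = 0.252 with an estimated correlation). NF-kB targets and cytokines had 16 lower and 4 higher of 25 (1 higher by TPM), the same adjusted over the list alone, with a median of −2.10 (camera adjusted p = 0.00473, adjusted p = 0.252 with an estimated correlation). Aryl hydrocarbon receptor targets had 5 lower of 7, led by Cyp1b1 (−9.07), again the same adjusted over the list alone. That list's median was −1.44 (camera adjusted p = 0.0123, adjusted p = 0.252 with an estimated correlation).

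Metabolic lists were higher in DKO DMSO. Of 24 cholesterol synthesis genes 21 were higher and 0 lower, and 22 and 1 adjusted over the list alone, with 15 higher without the WT DMSO 2-day library. Their median was 1.14 (camera adjusted p = 4.56e-06, adjusted p = 0.342 with an estimated correlation). The pathway genes Sqle and Mvk were higher by 1.91 and 1.75. Of 31 nuclear-encoded respiratory chain genes 22 were higher and 0 lower, the same adjusted over the list alone. The respiratory median was 0.89 (camera adjusted p = 6e-06, adjusted p = 0.0381 with an estimated correlation), with the ATP synthase gene Atp5b at 2504 ± 32.8 against 780 CPM (n = 2 each). Glycolysis and hypoxia genes had 17 higher and 2 lower of 24 (5 lower without the DKO DMSO 4-day library), the same adjusted over the list alone, including Eno1 and Pgk1 (1.75 each). Their median was 1.14 (camera adjusted p = 0.00795, adjusted p = 0.798 with an estimated correlation). Integrated stress response genes had 16 higher and 7 lower of 27 (3 lower without the WT DMSO 2-day library), with a median of 1.16 (camera adjusted p = 0.0123, adjusted p = 0.544 with an estimated correlation). Fatty acid synthesis genes had 14 and 4 of 19, with a median of 0.78 (camera adjusted p = 0.0123, adjusted p = 0.252 with an estimated correlation). Both counts were the same adjusted over the list alone. Slc7a5, which carries large neutral amino acids, was higher by 2.47, the serine synthesis gene Phgdh by 2.40 and the fatty acid synthase gene Fasn by 1.80. NRF2 targets had 13 higher and 3 lower of 21, and 14 and 4 adjusted over the list alone. Their median was 0.48 (camera adjusted p = 0.0437, adjusted p = 0.466 with an estimated correlation). By TPM, higher and lower members numbered 14 and 1 for cholesterol synthesis, 17 and 0 for the respiratory chain, 13 and 3 for hypoxia, 14 and 8 for the integrated stress response, 7 and 5 for fatty acid synthesis and 7 and 5 for NRF2 targets.

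The remaining lists did not pass in this comparison. Higher and lower members numbered 9 and 7 of 23 Hippo components (Lats1 and Lats2 left out), 11 and 5 of 17 Wnt targets, 12 and 6 of 28 G1/S genes, 16 and 8 of 28 G2/M genes, and 10 and 4 of 22 contractile genes. They numbered 7 and 5 of 15 TGF-beta targets, 7 and 8 of 20 unfolded protein response genes, 8 and 11 of 25 p53 targets, 5 and 2 of 13 mitochondrially encoded genes, and 4 and 8 of 16 immediate early genes. Among markers of other cell types, 6 and 3 of 12 adipocyte, 1 and 7 of 15 cartilage and bone, 3 and 1 of 8 skeletal muscle, 2 and 2 of 5 macrophage, 3 and 4 of 9 endothelial, 2 and 1 of 7 epithelial, and 3 and 3 of 9 neural genes were higher and lower. Neither of the 2 erythroid genes was called, and of the sex-linked list Xist, the X-inactivation RNA, was tested and was lower (−3.42). Its call was lost without the WT DMSO 2-day library, and the DKO DMSO libraries held 41 and 368 CPM of it. By TPM, higher and lower members numbered 3 and 7 for G1/S, 7 and 11 for G2/M, 4 and 6 for TGF-beta, 3 and 5 for neural genes, and 6 and 11 for Hippo components with Lats1 and Lats2. After ribosomal RNA and miRNA genes were removed they were 10 and 8 for G1/S and 15 and 11 for G2/M. By TPM 7 Wnt, 2 unfolded protein response, 4 p53, 3 mitochondrially encoded, 3 adipocyte and 2 immediate early genes were higher. Without the WT DMSO 2-day library 3 G1/S, 2 G2/M and, with Lats1 and Lats2, 5 Hippo genes were lower, and without the WT DMSO 4-day library 3 Wnt targets. Without the DKO DMSO 2-day library 3 cartilage and 4 epithelial genes were higher, and without the DKO DMSO 4-day library 8 mitochondrially encoded genes. HOX genes had 15 higher and 12 lower of 30, with a median of 0.42, a mean of −1.13 and a camera direction of down. Without the WT DMSO 2-day library 9 HOX genes were higher, and without the DKO DMSO 2-day library 6 were lower. In all, 10763 genes differed, 5260 higher and 5503 lower, and the count was 8894 in a fit of the 4 DMSO libraries alone. On the log2(TPM + 1) scale, where the median of all genes lay at −0.28, 31.5% of the calls were higher against 48.9% on counts.

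The second comparison asked what CP1 changed in WT cells. Interferon-stimulated genes fell. The antiviral gene Rsad2 stood at 5.14 ± 4.47 CPM (SD, n = 4) under CP1 against 295 ± 17.5 (n = 2) in DMSO, a log2 fold change of −6.21 (SE 0.54; edgeR adjusted p = 0.00034). Mx1 stood at 10.09 ± 7.66 against 325 ± 2.47 CPM, a log2 fold change of −5.38 (SE 0.48; edgeR adjusted p = 0.000398). Ifi44l (−7.17), Oas3 (−5.58) and the nucleic acid sensor gene Zbp1 (−5.57) fell too, as did Apod (−5.97). The near-identical GTPase genes Tgtp1 (−6.23) and Tgtp2 (−5.88), whose reads can be split between the paralogs, also fell. Ifi27, another interferon-inducible gene, rose by 2.48 (SE 0.09; edgeR adjusted p = 5.05e-09), to 287 ± 47.3 from 50.85 ± 2.45 CPM. The retinoic acid hydroxylase gene Cyp26b1 rose by 2.23 (SE 0.16; edgeR adjusted p = 2.55e-06) and the guanylate cyclase subunit gene Gucy1a1 by 2.04 (SE 0.14). The neuropeptide Y receptor gene Npy1r rose by 2.03, the glutathione transferase gene Gsta4 by 1.71 (SE 0.11), Aoc3 by 1.61, Adgrb2 by 1.54 and the fibroblast protease gene Fap by 1.49 (SE 0.17). Amotl2 fell by 0.43 on the log2 scale (SE 0.07; edgeR adjusted p = 0.000867) and Axl by 0.61 (SE 0.08; edgeR adjusted p = 0.000263). Ccn2 had a log2 fold change of −0.52 (SE 0.11; edgeR adjusted p = 0.00697), lost without the WT DMSO 2-day library (adjusted p = 0.314). A fit without 1 DMSO library of a genotype gives its CP1 effect at the other day, for Ccn2 −0.185 at 4 days. Ankrd1 had −1.45 (SE 0.34; edgeR adjusted p = 0.0099), lost without the WT DMSO 4-day library (−0.82, adjusted p = 0.382). Ccn1 (0.10), Tead4 (−0.28), Yap1 (−0.19), Wwtr1 (−0.07), Lats1 (−0.19), Tead1 (0.14), Tead2 (0.02) and Tead3 (0.09) did not pass. Without the DKO DMSO 2-day or 4-day library 4 of these passed at like sizes, Yap1 (adjusted p = 0.00108 and 0.00146), Lats1 (0.0145 and 0.0164), Tead4 (0.0235 and 0.0258) and Tead1 (0.0415 and 0.0339). Lats2 passed narrowly (−0.26, SE 0.08; edgeR adjusted p = 0.0337). Its call was lost with any of the 6 WT libraries left out, with adjusted p = 0.439 without the WT DMSO 2-day library.

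In WT cells 18 of 30 lists passed camera's test under CP1, and the NF-kB and nuclear-encoded respiratory chain lists held with an estimated correlation. All 30 interferon-stimulated genes fell, over all genes and adjusted over the list alone, and all 30 fell with each library left out. Their median was −3.25 (camera adjusted p = 3.7e-34, adjusted p = 0.107 with an estimated correlation). NF-kB targets and cytokines had 18 lower of 25, and 22 adjusted over the list alone, with 13 lower without the WT DMSO 2-day library. Their median was −0.83 (camera adjusted p = 7.61e-14, adjusted p = 0.0172 with an estimated correlation). The chemokine gene Cxcl10 fell from 318 to 8.94 ± 2.18 CPM (log2 fold change −5.19, SE 0.17; edgeR adjusted p = 2.76e-08), while Ccl2 and Ccl7 had log2 fold changes of −1.84 and −1.69. YAP/TAZ-TEAD targets had 9 lower and 0 higher of 21, and 12 and 1 adjusted over the list alone, with the coagulation initiator gene F3 at −0.65 (SE 0.07). Their median was −0.31 (camera adjusted p = 0.00119, adjusted p = 0.0739 with an estimated correlation), and 5 were lower without the WT DMSO 2-day library. In 3 WT CP1 libraries, 2 days repeat 1 and both 4-day repeats, ribosomal RNA genes held 2.61%, 2.18% and 2.06% of counts, against 0.03% in the other WT CP1 library and in WT DMSO. Without these 3 libraries 30 interferon-stimulated, 7 NF-kB and 1 YAP/TAZ-TEAD gene were lower.

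**Figure D2:**
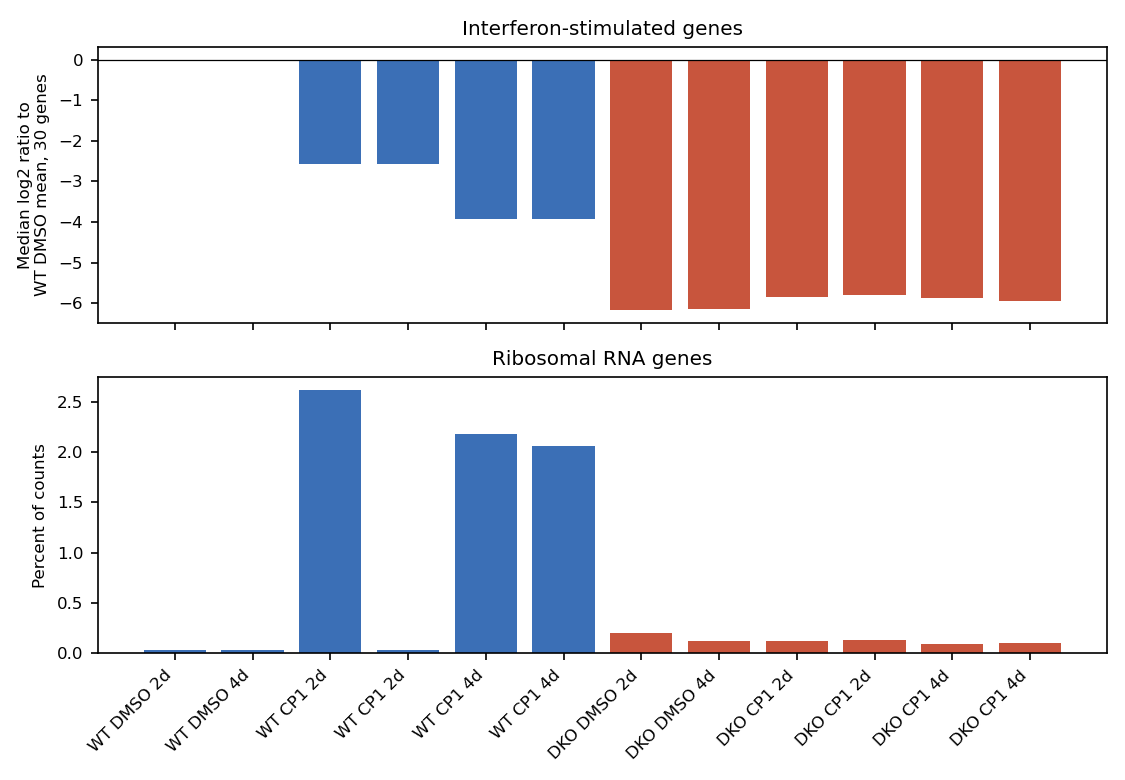
Bars show, per library, the median log2 ratio of 30 interferon-stimulated genes to the WT DMSO mean and the percent of counts in ribosomal RNA genes. The WT CP1 2-day repeats stood at −2.57 and −2.56 although the ribosomal RNA share was 2.61% in one and 0.03% in the other, and the 4-day repeats stood at −3.93 and −3.92.

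Matrix genes had 19 lower and 0 higher of 33 under CP1 in WT, and 24 and 1 adjusted over the list alone, including Fbln5 (−0.82, SE 0.07), the metalloproteinase inhibitor gene Timp1 (−0.98) and Tnc (−0.84). Their median was −0.42 (camera adjusted p = 4.5e-08, adjusted p = 0.129 with an estimated correlation). Immediate early genes had 11 lower of 16, and 13 adjusted over the list alone, with Egr1 at −1.16 (SE 0.10). Their median was −0.58 (camera adjusted p = 1.17e-07, adjusted p = 0.129 with an estimated correlation). TGF-beta targets had 7 lower of 15, and 8 adjusted over the list alone, among them Tgif1 (−0.93). Their median was −0.30 (camera adjusted p = 0.000496, adjusted p = 0.129 with an estimated correlation). Integrated stress response genes had 11 lower and 1 higher, and 15 and 1 adjusted over the list alone, with Atf3 at −1.14 (list camera adjusted p = 0.000158, adjusted p = 0.207 with an estimated correlation). Unfolded protein response genes had 10 lower, and 13 adjusted over the list alone, with Pdia3 at −0.55 (list camera adjusted p = 4.72e-05, adjusted p = 0.129 with an estimated correlation). The p53 targets had 8 lower and 1 higher (camera adjusted p = 0.00698, adjusted p = 0.227 with an estimated correlation). Hippo components had 6 lower (camera adjusted p = 0.0463, adjusted p = 0.245 with an estimated correlation). Aryl hydrocarbon receptor targets had 3 lower (camera adjusted p = 0.000757, adjusted p = 0.0739 with an estimated correlation). Macrophage markers had 2 lower, Mpeg1 and Cd14 (camera adjusted p = 0.0465, adjusted p = 0.129 with an estimated correlation). Adjusted over the list alone these last 4 lists had 9, 9, 6 and 2 lower members. Without the WT DMSO 2-day library the lower members numbered 6 immediate early, 4 integrated stress response, 4 unfolded protein response, 2 Hippo and 2 aryl hydrocarbon receptor genes. They numbered 11 matrix genes and 2 p53 targets without the WT DMSO 4-day library, and 4 TGF-beta targets without the WT CP1 4-day repeat 1. Without the 3 libraries rich in ribosomal RNA, which leaves 1 WT CP1 library, 3 matrix, 2 immediate early, 1 integrated stress response, 1 aryl hydrocarbon receptor and 1 macrophage gene were called lower by edgeR, and 0 of the other lists in this paragraph.

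Some mitotic, contractile and respiratory genes were called higher in WT cells under CP1 on the count scale. G2/M genes had 14 higher of 28, and 18 adjusted over the list alone, including the cyclin genes Ccnb2 (0.42) and Ccnb1 (0.41). Their median was 0.31 (camera adjusted p = 1.49e-07, adjusted p = 0.129 with an estimated correlation). Contractile and SRF-target genes had 7 higher of 22, and 7 with 1 lower adjusted over the list alone. Their median was 0.26 (camera adjusted p = 0.000452, adjusted p = 0.107 with an estimated correlation). Smooth muscle actin Acta2 rose by 0.84 (SE 0.09; edgeR adjusted p = 2.05e-05), to 1119 ± 100 from 622 CPM, and the myosin light chain gene Myl9 by 0.85 (SE 0.07; edgeR adjusted p = 1.49e-06). Nuclear-encoded respiratory chain genes had 9 higher of 31, and 11 adjusted over the list alone. Their median was 0.19 (camera adjusted p = 1.81e-06, adjusted p = 0.0172 with an estimated correlation). Mitochondrially encoded genes had 7 higher of 13, and 9 adjusted over the list alone. Their median was 0.38 (camera adjusted p = 4.72e-05, adjusted p = 0.107 with an estimated correlation). Fatty acid synthesis genes had 5 higher, including Scd1 (0.64; list camera adjusted p = 0.00801, adjusted p = 0.129 with an estimated correlation). HOX genes had 4 higher, including Hoxa9 (0.38; list camera adjusted p = 0.0484, adjusted p = 0.129 with an estimated correlation). Both counts were the same adjusted over the list alone. Higher members by TPM numbered 0 G2/M, 2 contractile, 0 nuclear-encoded respiratory chain, 2 mitochondrially encoded, 1 fatty acid and 0 HOX genes, and 1 contractile and 1 HOX gene were lower. After ribosomal RNA and miRNA genes were removed they numbered 18, 10, 23, 9, 9 and 6, with 0 lower in each list. The counts were 0 G2/M, 4 contractile and 0 mitochondrially encoded genes without the WT DMSO 4-day library. They were 1 respiratory chain, 2 fatty acid and 1 HOX gene without the WT DMSO 2-day library. Without either DKO DMSO library 25 G2/M, 20 respiratory chain and 13 contractile genes were higher. Without the 3 libraries rich in ribosomal RNA 2 contractile genes were higher and 0 of the others.

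In all, CP1 changed 2954 genes in WT cells, 1244 higher and 1710 lower. The count was 1428 and 1283 without the WT DMSO 2-day or 4-day library, and 5238 and 5256 without the DKO DMSO 2-day or 4-day library, which enter the shared estimate of spread. It was 5987 with 8 group means and 345 without the 3 libraries rich in ribosomal RNA. By TPM, where the median of all genes lay at −0.14, 7.7% of calls were higher against 42.1% on counts, and 68.8% after ribosomal RNA and miRNA genes were removed, with the median at 0.10.

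The third comparison asked what CP1 changed in DKO cells. Several YAP/TAZ-TEAD genes that were high in DKO DMSO fell. Ankrd1 fell from 48.32 to 15.53 ± 1.46 CPM (n = 4; log2 fold change −1.64, SE 0.14; edgeR adjusted p = 8.98e-07). Ccn2 fell from 181 ± 16.2 (n = 2) to 87.07 ± 1.86 CPM (−1.06, SE 0.11; edgeR adjusted p = 5.91e-06). Axl fell from 1384 to 704 ± 20.3 CPM (−0.97, SE 0.08; edgeR adjusted p = 1.27e-06) and Amotl2 from 1315 to 800 ± 25.9 (−0.72, SE 0.07; edgeR adjusted p = 3.11e-06). Tead4 fell by 1.23 on the log2 scale (SE 0.10; edgeR adjusted p = 5.31e-07), Ccn1 by 0.48 (edgeR adjusted p = 0.00129) and Tead2 by 0.39 (edgeR adjusted p = 0.00191). Tead1 (−0.46, edgeR adjusted p = 0.00315) lost its call without the DKO DMSO 4-day library, a fit that gives the effect at 2 days (−0.15, adjusted p = 0.0783). Yap1 (−0.32, edgeR adjusted p = 0.0171) lost it without the DKO DMSO 2-day library (−0.01, adjusted p = 0.879) or either DKO CP1 2-day repeat (adjusted p = 0.0615 and 0.0551). Lats1 rose by 0.92 (SE 0.11; edgeR adjusted p = 1.96e-05), while Lats2 (0.03, adjusted p = 0.821), Wwtr1 (−0.17) and Tead3 (−0.04) did not pass. Without the DKO DMSO 2-day library Wwtr1 (−0.26, adjusted p = 0.00196) and Tead3 (−0.22, adjusted p = 0.0126) did, as did Wwtr1 without the DKO CP1 2-day repeat 2 (−0.21, adjusted p = 0.0245).

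Genes that rose from near 0 in DKO cells included the angiotensin receptor gene Agtr2 (at least 91.0-fold; 7.56 ± 6.75 CPM, n = 4), the corneal proteoglycan gene Kera (at least 87.5-fold) and Fap (at least 15.9-fold). The potassium channel subunit gene Dpp10 rose at least 10.4-fold, and the scavenger receptor gene Scara5 had 1024 against 1 count, a ratio of 448 (95% interval 80.3 to 17720). Thy1 rose at least 5.25-fold (edgeR adjusted p = 0.0314). Its call was lost with any 1 of 7 libraries left out, with the highest adjusted p at 0.251 without the DKO DMSO 4-day library. The chemokine gene Cxcl15 rose by 8.27 (SE 0.42; edgeR adjusted p = 4.29e-07) and the protease inhibitor gene Serpina3n by 6.23 (SE 0.24). Wnt7a fell from 72.0 ± 0.44 to 4.45 ± 0.26 CPM (log2 fold change −4.02, SE 0.15; edgeR adjusted p = 1.51e-09). The junctophilin gene Jph2 (−5.07), the BMP antagonist gene Nog (−3.78), the keratin gene Krt7 (−3.42) and Fxyd6 (−3.40) fell too. So did the interferon- or cytokine-induced genes Ccl5 (−4.60), Cxcl10 (−3.78) and Oasl1 (−3.37). The 2 DKO DMSO libraries differed from each other more than any CP1 repeat pair, with a chi-square per degree of freedom of 43.42 against 2.25 to 5.82. Xist stood at 41 and 368 CPM in them and at 781 to 969 in DKO CP1.

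**Figure D3:**
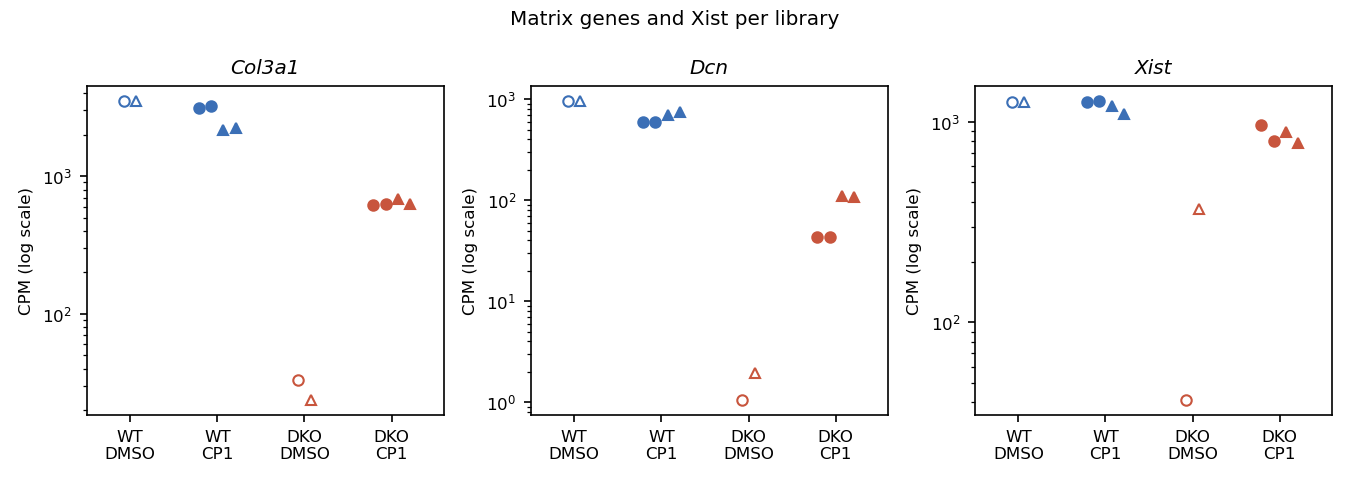
CPM, on a log axis, of Col3a1, Dcn and Xist in each library (blue, WT; red, DKO; open symbols, DMSO; filled symbols, CP1; circles, 2 days; triangles, 4 days). Col3a1 stood at 33.2 and 23.7 in DKO DMSO and at 615 to 682 in DKO CP1, against 3519 and 3500 in WT DMSO.

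Matrix and fibroblast genes rose under CP1 in DKO cells, where 10 of 30 lists passed and only the respiratory chain list held with an estimated correlation. Of 33 matrix genes 20 rose and 5 fell, the same adjusted over the list alone, and 3 fell without the DKO CP1 4-day repeat 1 and 1 by TPM. Their median was 0.65 (camera adjusted p = 2.43e-05, adjusted p = 0.418 with an estimated correlation). The fibrillar collagen gene Col3a1 rose from 28.4 to 638 ± 29.7 CPM (n = 4; log2 fold change 4.50, SE 0.17; edgeR adjusted p = 1.51e-09). Dcn rose from 1.49 to 76.2 ± 38.0 (5.65, SE 0.14; edgeR adjusted p = 8.64e-11) and Fbln1 from 11.1 to 140 ± 35.5 (3.62, SE 0.12; edgeR adjusted p = 6.82e-10). Fibroblast markers had 13 higher and 2 lower of 17, the same adjusted over the list alone, and 8 higher without the DKO DMSO 4-day library. Their median was 1.22 (camera adjusted p = 0.000598, adjusted p = 0.418 with an estimated correlation), with Prrx1 up by 1.86 (SE 0.08). Aryl hydrocarbon receptor targets had 5 higher of 7, and 6 adjusted over the list alone, with Cyp1b1 up by 4.68 and Ahr by 1.59. Their median was 1.59 (camera adjusted p = 0.000977, adjusted p = 0.0828 with an estimated correlation). YAP/TAZ-TEAD targets had 15 lower and 2 higher of 21, the same adjusted over the list alone, and 8 and 4 by TPM. Their median was −0.55 (camera adjusted p = 0.00226, adjusted p = 0.0828 with an estimated correlation). Contractile genes had 18 lower and 3 higher of 22, the same adjusted over the list alone, and 10 and 3 by TPM. Their median was −0.69 (camera adjusted p = 4.67e-05, adjusted p = 0.0828 with an estimated correlation). The focal adhesion gene Zyx stood at −2.06 (SE 0.12; edgeR adjusted p = 7.6e-08), Actn1 at −0.95 and Acta2 at −0.92.

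Nuclear-encoded respiratory chain genes had 24 lower and 2 higher of 31 in DKO cells under CP1, 24 and 3 adjusted over the list alone, and 10 and 4 by TPM. Their median was −0.44 (camera adjusted p = 1.4e-05, adjusted p = 0.0362 with an estimated correlation), with Uqcrc1 at −1.10 (SE 0.07; edgeR adjusted p = 4.97e-08). G1/S genes had 17 lower and 3 higher of 28, and 18 and 3 adjusted over the list alone, but 4 and 4 by TPM. Their median was −0.37 (camera adjusted p = 0.00324, adjusted p = 0.596 with an estimated correlation), with the ribonucleotide reductase gene Rrm2 at −1.27 (SE 0.08). Glycolysis and hypoxia genes had 14 lower and 1 higher, the same adjusted over the list alone, but 4 and 3 by TPM, and 6 lower and 8 higher without the DKO DMSO 4-day library. Their median was −0.48 (camera adjusted p = 0.0451, adjusted p = 0.809 with an estimated correlation). NRF2 targets had 13 lower and 5 higher, the same adjusted over the list alone, but 4 and 5 by TPM. Their median was −0.44 (camera adjusted p = 0.0451, adjusted p = 0.596 with an estimated correlation). The p53 targets had 15 lower and 5 higher, and 15 and 6 adjusted over the list alone, but 6 and 7 by TPM. Their median was −0.48 (camera adjusted p = 0.0451, adjusted p = 0.596 with an estimated correlation). By TPM after ribosomal RNA and miRNA genes were removed, lower and higher members numbered 9 and 4 YAP/TAZ-TEAD, 15 and 3 contractile, and 16 and 7 respiratory chain genes. They numbered 8 and 8 G1/S, 6 and 4 hypoxia, 9 and 6 NRF2 and 11 and 8 p53 genes. Interferon-stimulated genes, with 9 higher and 4 lower, did not pass (camera adjusted p = 0.138), nor did NF-kB targets, with 11 and 8 (camera adjusted p = 0.2). Without the DKO DMSO 4-day library 1 interferon-stimulated gene was higher, and without either WT DMSO library 18 were. By TPM 17 were higher and 3 lower. The siderophore-binding protein gene Lcn2 rose by 3.13 (SE 0.13). In all, 8608 genes were called, 4023 higher and 4585 lower, of which 1843 and 703 changed at least 2-fold. On the TPM scale, where the median of all genes lay at 0.22, 79.9% of the calls were higher against 46.7% on counts, and 74.9% after ribosomal RNA and miRNA genes were removed.

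**Figure D4:**
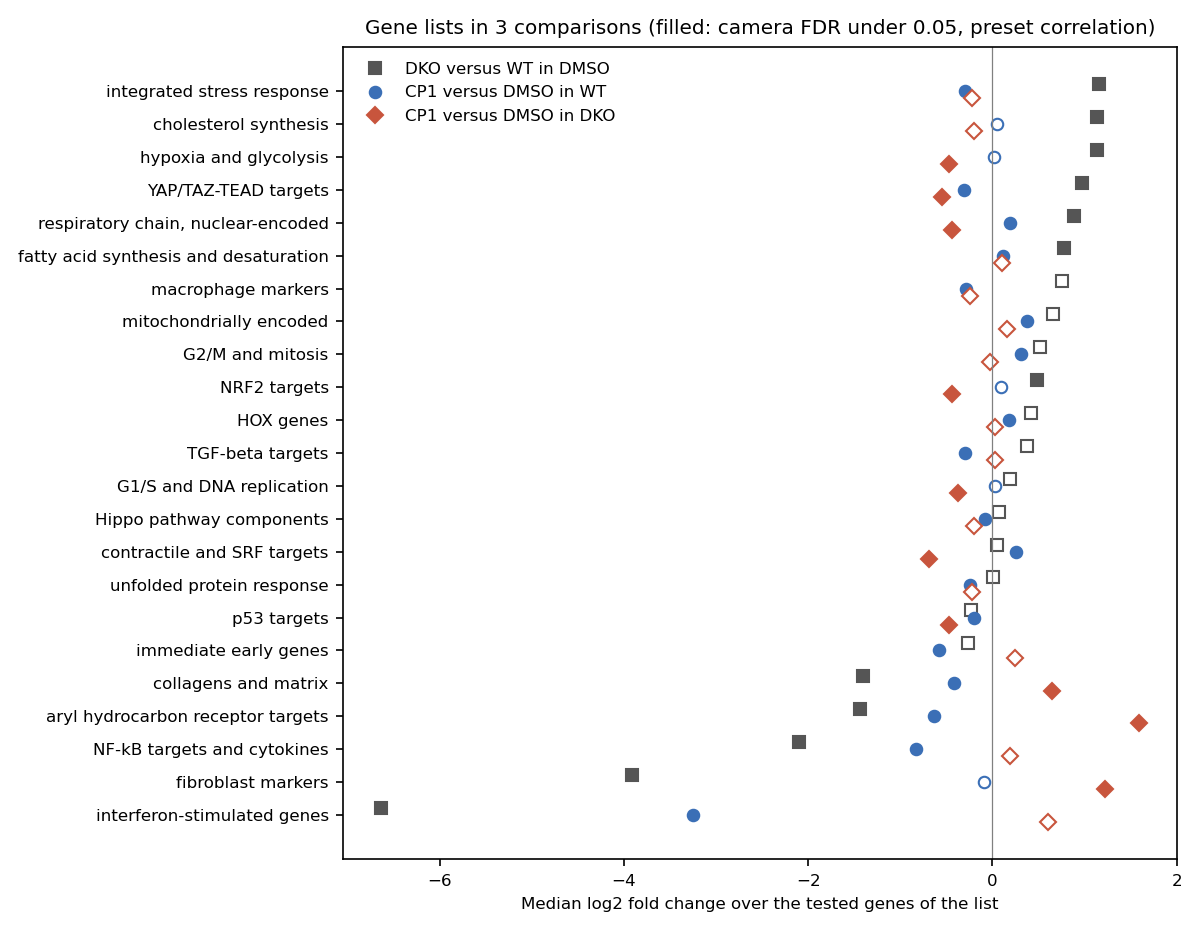
Median log2 fold change of 23 gene lists in 3 comparisons (DKO against WT in DMSO, CP1 in WT, CP1 in DKO), with filled points for lists that passed camera's test at a preset correlation. The matrix list stood at −1.41, −0.42 and 0.65, and the interferon-stimulated list at −6.64 in the first comparison and −3.25 in WT cells under CP1.

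The fourth comparison asked whether the CP1 effect differed between genotypes, by the difference of the log2 fold changes, DKO minus WT. Interferon-stimulated genes, which fell in WT cells, differed upwards in 29 of 30 members, the same adjusted over the list alone, and in 21 without the DKO DMSO 2-day library. Their median difference was 3.96 (camera adjusted p = 7.61e-16, adjusted p = 0.377 with an estimated correlation). Matrix genes differed upwards in 26 of 33 and downwards in 0, the same adjusted over the list alone, with Dcn at 6.19 and Col3a1 at 4.91 (SE 0.20; edgeR adjusted p = 3.82e-09). Their median was 0.99 (camera adjusted p = 2.26e-11, adjusted p = 0.133 with an estimated correlation). Contractile genes differed downwards in 18 and upwards in 2 of 22, the same adjusted over the list alone, with Acta2 at −1.76 (SE 0.12; edgeR adjusted p = 3.33e-07). Their median was −1.05 (camera adjusted p = 9.12e-07, adjusted p = 0.0576 with an estimated correlation). Respiratory chain genes differed downwards in 26 of 31, and 27 adjusted over the list alone, but 2 were lower and 2 higher by TPM, and 20 and 0 after ribosomal RNA and miRNA genes were removed. Their median was −0.67 (camera adjusted p = 1.64e-09, adjusted p = 0.0102 with an estimated correlation). NF-kB targets had 15 upwards and 1 downwards, and 15 and 2 adjusted over the list alone. Their median was 1.14 (camera adjusted p = 5.98e-06, adjusted p = 0.0794 with an estimated correlation). Fibroblast markers had 9 upwards, and 11 adjusted over the list alone. Their median was 1.54 (camera adjusted p = 0.000249, adjusted p = 0.343 with an estimated correlation). Aryl hydrocarbon receptor targets had 6 upwards, the same adjusted over the list alone. Their median was 2.02 (camera adjusted p = 0.000123, adjusted p = 0.0576 with an estimated correlation). Immediate early genes had 10 upwards and 1 downwards, and 10 and 2 adjusted over the list alone. Their median was 0.64 (camera adjusted p = 0.0073, adjusted p = 0.487 with an estimated correlation). G1/S genes had 15 downwards and 1 upwards, and 16 and 1 adjusted over the list alone, but 1 and 3 by TPM, and 9 and 3 after that removal. Without the WT DMSO 4-day library 10 G1/S genes differed downwards. Their median was −0.38 (camera adjusted p = 0.00216, adjusted p = 0.483 with an estimated correlation). NRF2 targets had 13 downwards and 4 upwards, the same adjusted over the list alone, but 2 and 6 by TPM, and 12 and 5 after that removal. Their median was −0.52 (camera adjusted p = 0.0188, adjusted p = 0.377 with an estimated correlation). The YAP/TAZ-TEAD list did not pass, with 8 downwards and 1 upwards, and 0 and 4 by TPM, or 2 and 2 after that removal (camera adjusted p = 0.186). It had 3 downwards without the WT DMSO 4-day library, 11 downwards and 3 upwards without the DKO DMSO 4-day library, and 0 each way without the 3 WT CP1 libraries rich in ribosomal RNA. Without these 3 libraries, which leaves 1 WT CP1 library, 17 matrix, 5 immediate early and 4 aryl hydrocarbon receptor genes differed upwards. Those downwards then numbered 16 respiratory chain, 4 NRF2 and 2 G1/S genes.

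The largest differences upwards among single genes were Apod (10.7), Kera (9.83), Cxcl15 (9.78), Agtr2 (9.16), Scara5 (8.13), the interferon-inducible genes Phf11b (7.13) and Slfn8 (6.96), and Dpp10 (6.9), where fitted values of genes at or near 0 counts depend on the prior count. Those downwards were Jph2 (−4.24), Wnt7b (−3.95), Aldh1a7 (−3.85), Wnt7a (−3.61), the phosphatase gene Dusp4 (−3.34), Siglecg (−3.23), the Wnt-pathway receptor gene Lgr6 (−3.09) and Aldh1a1 (−2.96). Wnt7a lost its call without the WT DMSO 4-day library (−1.64, edgeR adjusted p = 0.392), and Aldh1a1 with any 1 of 6 libraries left out (highest adjusted p = 0.265, without the WT DMSO 4-day library). Wnt7b lost it without the WT CP1 2-day repeat 1 (−3.085, adjusted p = 0.277) or the WT DMSO 2-day library (−3.275). Lats1 differed by 1.1 (SE 0.15; edgeR adjusted p = 7.2e-05) and Tead4 by −0.95 (edgeR adjusted p = 0.000189). Smaller differences that passed were Tead1 (−0.6), Tead2 (−0.41), Ccn1 (−0.58), Ccn2 (−0.54), Amotl2 (−0.28) and Axl (−0.36), each lost with at least 1 library left out. Their highest adjusted p values were 0.0654, 0.15, 0.0643, 0.19, 0.119 and 0.139. By TPM the direction turned for Tead2 (0.094), Amotl2 (0.216) and Axl (0.144), and after ribosomal RNA and miRNA genes were removed for Dpp10 (−0.051). Ankrd1 (−0.19), Lats2 (0.29), Yap1 (−0.14), Wwtr1 (−0.10) and Tead3 (−0.13) did not pass. Without the DKO DMSO 4-day library Yap1 passed (−0.42, edgeR adjusted p = 5.27e-05). Tead3 (−0.30, adjusted p = 0.00631) and Lats2 (0.40, adjusted p = 0.0166) passed without the DKO DMSO 2-day library, and Lats2 also without the WT DMSO 4-day library (0.39, adjusted p = 0.0474). In all, 7040 genes differed, 3342 upwards and 3698 downwards, with 2419 left without the 3 WT CP1 libraries rich in ribosomal RNA. On the TPM scale, where the median of all genes lay at 0.38, 91.3% of the calls were upwards against 47.5% on counts, and 63.8% after ribosomal RNA and miRNA genes were removed.

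Averaged over both genotypes, CP1 lowered the chemokine genes Cxcl10 (log2 fold change −4.48, SE 0.12; edgeR adjusted p = 1.22e-08) and Ccl5 (−4.86), with Oasl1 (−3.91), Tgtp2 (−3.69) and Zbp1 (−3.05). It raised Gucy1a1 by 2.90 (SE 0.19; edgeR adjusted p = 2.21e-07). Agtr2 (5.73), Fap (4.66), Dpp10 (3.77) and Thy1 (3.19) led the higher genes, from counts of 0 in DKO DMSO. YAP/TAZ-TEAD targets had 16 lower and 2 higher of 21, the same adjusted over the list alone. Their median was −0.42 (camera adjusted p = 0.000752, adjusted p = 0.131 with an estimated correlation). Unfolded protein response genes had 13 lower and 1 higher of 20, the same adjusted over the list alone. Their median was −0.29 (camera adjusted p = 0.00221, adjusted p = 0.405 with an estimated correlation). In all, 6957 genes were called, 3201 higher and 3756 lower, and 2577 without the 3 WT CP1 libraries rich in ribosomal RNA. By TPM 58.8% of the calls were higher against 46% on counts, and 79.2% after ribosomal RNA and miRNA genes were removed, where the median of all genes lay at 0.16.

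With both genotypes under CP1, DKO cells had higher YAP/TAZ-TEAD targets, with 14 higher and 2 lower of 21, the same adjusted over the list alone. Their median was 0.65 (camera adjusted p = 0.000501, adjusted p = 0.142 with an estimated correlation). Cholesterol synthesis genes had 21 higher and 1 lower of 24, and integrated stress response genes 20 and 2 of 27. Adipocyte genes had 9 and 2 of 12, and fibroblast markers 2 higher and 12 lower of 17. Each count was the same adjusted over the list alone. In that order the medians were 0.93, 1.02, 0.50 and −0.88. Camera adjusted p values were 2.25e-08, 1.08e-06, 0.00787 and 0.00232, and 0.307, 0.251, 0.185 and 0.328 with an estimated correlation. Interferon-stimulated genes were lower in 28 of 30, and 29 adjusted over the list alone. Their median was −2.62 (camera adjusted p = 5.39e-11, adjusted p = 0.434 with an estimated correlation). Of single genes, the chemokine gene Ppbp was higher by 6.42 (SE 0.22; edgeR adjusted p = 2.37e-09), Pkp1 by 6.18, the phosphatase gene Ppef1 by 5.80 and the forkhead gene Foxd1 by 5.68. Tlx2 had 997 against 2 counts, a ratio of 628 (95% interval 174 to 5196). Pdgfd was at least 1012-fold, Hoxd11 at least 859-fold and the kinase gene Nrk at least 513-fold lower. Prr16 had 1 count in DKO cells, a ratio of 2128 (95% interval 382 to 84070), and Gda was lower by a log2 fold change of −11.41. Of 8582 genes called, 4140 were higher and 4442 lower, with 5253 called without the 3 WT libraries rich in ribosomal RNA. By TPM, where the median of all genes lay at 0.13, 62.6% of the calls were higher against 48.2% on counts. The share was 47.3% after ribosomal RNA and miRNA genes were removed, with the median at −0.03.

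Effects of CP1 were also fitted at each day, where each contrast rested on a single DMSO library whose spread was taken from the other groups. In WT cells at 2 days Rsad2 fell to 9.01 ± 0.27 CPM (n = 2) from 282 (log2 fold change −4.97; edgeR adjusted p = 5.07e-25), and at 4 days to 1.28 ± 0.21 from 307. Ifi44l fell at both days (−6.29 and −9.07), as did Tgtp1 (−5.49 and −7.40), Tgtp2 (−5.19) and Cxcl10 (−4.83) at 2 days and Apod (−7.40) and Oas3 (−7.14) at 4 days. Ifi27 rose by 2.64 and 2.33, Npy1r by 2.58 and 1.66 and Gucy1a1 by 2.15 and 1.92, with Aoc3 (1.97) and Gsta4 (1.90) at 2 days and Cyp26b1 (2.65) and the G-protein regulator gene Rgs2 (1.59) at 4 days. In DKO cells at 2 days Jph2 (−5.09), Wnt7a (−4.08), Ccl5 (−3.54), Nog (−3.51) and Krt7 (−3.45) fell. Genes with 0 counts in the lone DMSO library reached 7.29 ± 1.56 CPM for Scara5, 3.27 ± 1.58 for Kera, 2.54 ± 0.21 for the DNA demethylation gene Tet1, 2.19 ± 0.28 for Pi15 and 1.73 ± 0.62 for Agtr2 (n = 2 each). At 4 days Agtr2 reached 13.4 ± 0.29, Kera 11.43 ± 0.76 and Fap 1.94 ± 0.21 CPM from 0 counts, and Cxcl15 rose by 8.66 and Scara5 by 8.13, from 1 count. At that day Ccl5 (−5.85), Jph2 (−5.04), Krt19 (−4.15), Cxcl10 (−4.13) and Nog (−4.05) fell. In WT cells 4232 genes were called at 2 days and 4202 at 4 days, of which 44.1% and 45.3% were higher. In DKO cells 9331 and 8071 were called, with 48.2% and 44.9% higher. The shares on the TPM scale were 16.5%, 6.7%, 82.4% and 79.1%, and 66.5%, 71.7%, 72.3% and 72.9% after ribosomal RNA and miRNA genes were removed. Without the WT CP1 2-day library rich in ribosomal RNA 2414 genes were called at 2 days in WT.

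Between 4 and 2 days under CP1, Oas2 fell further in WT cells, to 12.33 ± 1.15 from 74.24 ± 1.24 CPM (n = 2 each; log2 fold change −2.59; edgeR adjusted p = 1.4e-20), as did Slfn5 (−2.99), Rsad2 (−2.81), Ifi44l (−2.78) and Apod (−2.72). The acute-phase gene Hp rose to 30.97 ± 0.7 from 7.25 ± 0.01 CPM (2.09; edgeR adjusted p = 1.43e-13), with U90926 (1.85), Kirrel3 (1.59), the placental-hormone family gene Prl2c2 (1.47), whose near-identical copies can share reads, and Dusp4 (1.43). In DKO cells the homeobox gene Meox2 (2.51), Agtr2 (2.96), Pcdh17 (2.07), Kera (1.81) and the lipase inhibitor gene Angptl4 (1.64) rose, and the imprinted gene Peg3 (−3.60), the necroptosis kinase gene Ripk3 (−3.08), Ak4 (−2.59), Krt19 (−2.43) and the lubricin gene Prg4 (−2.06) fell. In WT cells 2532 genes were called, with 1362, 1172, 1336 and 1256 left when 1 of the 4 WT CP1 libraries was left out (2-day repeats 1 and 2, then 4-day repeats 1 and 2). In DKO cells 4012 were called, with 2179 left without the DKO CP1 4-day repeat 1. Higher calls made up 45.9% and 50.2% on counts, and 9.3% and 31.1% on the TPM scale, or 52.9% and 47.8% after ribosomal RNA and miRNA genes were removed. Between the single DMSO libraries of 4 and 2 days, edgeR called 0 genes in WT cells, where 485 had an unadjusted p under 0.05, and 4659 in DKO cells, and no other tool was run for these. Contrasts of the CP1 effect at 4 minus 2 days called 557 genes in WT and 4547 in DKO. They hold 1 DMSO library per day, and the 4659 calls between the DKO DMSO libraries enter them, so they are not read as a day difference of the CP1 effect. The WT count was 307 without the WT CP1 2-day repeat 2 and 1286 and 1287 without the DKO CP1 2-day repeats. Of these 28% and 50.3% were higher on counts, and 17.3% and 9.9% on the TPM scale, or 21.9% and 42% after that removal.

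The last comparison asked how the CP1 effect in DKO cells related to the genotype effect, across genes, which are not independent replicates. With the effects taken from disjoint libraries, the genotype effect at one day against the CP1 effect at the other, Pearson's r was −0.45 and −0.416 (Spearman's rho −0.548 and −0.507), with slopes of −0.233 and −0.264, over 16595 genes. With the DKO DMSO libraries shared, r was −0.616 (rho −0.667) and the covariance −1.423, against −0.504 and −0.065 in 10 simulations of unchanged groups. Of genes higher in DKO DMSO, 3572 fell under CP1, where independent lists would share 1453.3, and of those lower, 2944 rose (independent lists, 1334.1). Part of this excess may come from the shared controls. With disjoint libraries, the genotype effect at 2 or at 4 days and the CP1 effect at the other day, 3375 and 3285 of the higher genes fell (independent lists, 1469.2 and 1521.7). Of the lower genes 2597 and 2649 rose (independent lists, 1271.1 and 1483). Of the 2421 genes called at least 2-fold higher in DKO than WT in DMSO, 91.1% differed less under CP1 (median 1.54 in DMSO and 0.81 under CP1), and of the 3729 lower ones 90.5% (−2.32 and −1.03). Genes chosen for a large difference tend to differ less in other libraries by that choice alone. With the choice made under CP1, a test added after the results were seen, 46.4% of 1336 higher and 29.6% of 2043 lower genes differed less in DMSO. CP1 effects in WT and in DKO cells had r = −0.012 across genes (rho 0.014). Of their calls, 461 genes were lower in both, where independent lists would share 472.5, and 358 were higher in both, against 301.6. Opposite calls numbered 421 higher in WT and lower in DKO (independent lists, 343.7), and 542 the other way (independent lists, 414.5).

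**Figure D5:**
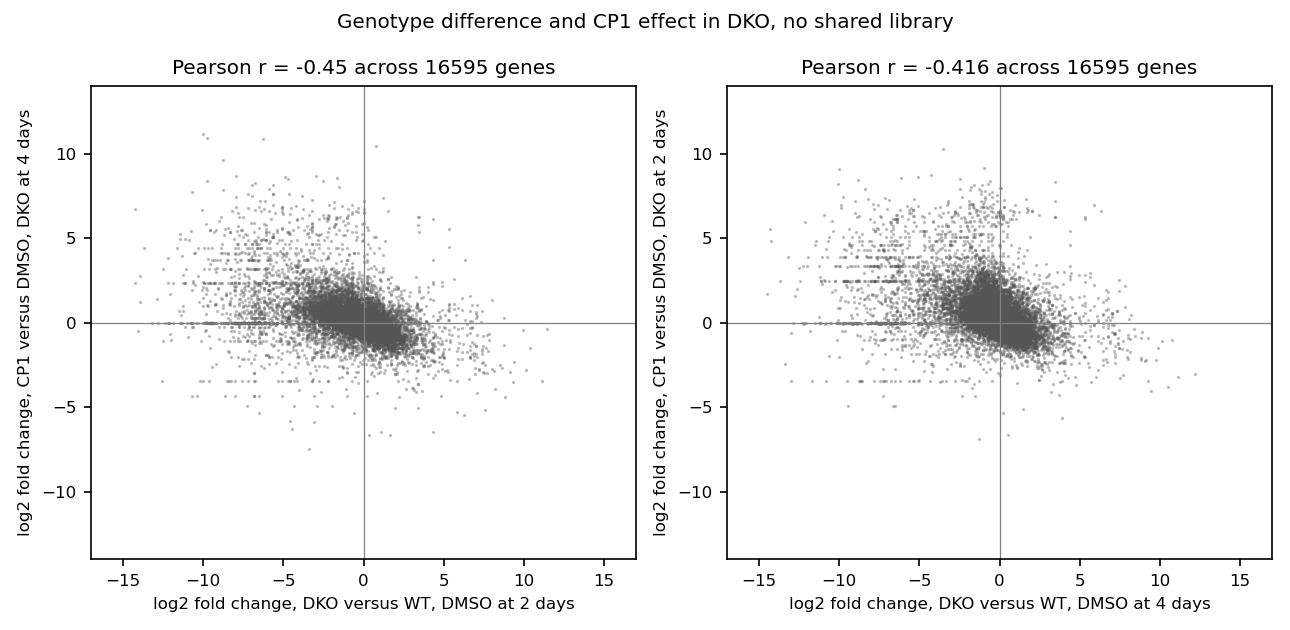
Each point is 1 of 16595 genes, with the log2 fold change of DKO against WT in DMSO at one day on the x axis and that of CP1 against DMSO in DKO cells at the other day on the y axis, so that no library enters both. Pearson's r across genes was −0.45 and −0.416 in the 2 panels.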

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

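The tests of WT or undeleted cells in the DKO cultures, of an Xist-marked cell share, of the ribosomal RNA batch, of macrophages and of a response of the WT DMSO cultures alone were chosen after the results were seen, and the counts of other sample splits were planned, with their bounds written afterwards. The bound of the Xist test was changed after its value was known.

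The CP1 effect differed between genotypes, by the test of the difference itself, for 7040 genes. Between 4 and 2 days edgeR called a difference for 557 genes in WT and 4547 in DKO cells. With 1 DMSO library per genotype and day, these are not read as a day difference of the CP1 effect. The DKO DMSO libraries alone differed at 4659 genes. Lists whose response differed between genotypes, as the median log2 difference DKO minus WT, were interferon-stimulated genes (3.96), aryl hydrocarbon receptor targets (2.02), fibroblast markers (1.54), NF-kB targets (1.14), matrix (0.99), immediate early genes (0.64), G1/S (−0.38), NRF2 targets (−0.52), respiratory chain (−0.67) and contractile genes (−1.05). On the TPM scale the calls of G1/S and NRF2 members were mostly upwards, and 2 respiratory chain genes were called each way. After ribosomal RNA and miRNA genes were removed, 9 G1/S, 12 NRF2 and 20 respiratory chain genes were downwards and 3, 5 and 0 upwards. With an estimated correlation only the respiratory chain list held (adjusted p = 0.0102), and the others lay between 0.0576 and 0.487. Pathway genes that differed were Lats1 (1.1), Tead1 (−0.6), Tead2 (−0.41), Tead4 (−0.95), Ccn1 (−0.58), Ccn2 (−0.54), Amotl2 (−0.28) and Axl (−0.36). By TPM the direction turned for Tead2, Amotl2 and Axl. Amotl2 and Axl each lost the call with any 1 of 9 libraries left out. Larger differences upwards were Apod (10.7), Kera (9.83), Cxcl15 (9.78), Agtr2 (9.16), Scara5 (8.13), Phf11b (7.13), Slfn8 (6.96) and Dpp10 (6.9). Those downwards were Jph2 (−4.24), Wnt7b (−3.95), Aldh1a7 (−3.85), Wnt7a (−3.61), Dusp4 (−3.34), Siglecg (−3.23), Lgr6 (−3.09) and Aldh1a1 (−2.96). The contrasts of the CP1 effect at 4 minus 2 days give differences of CP1 effects, not levels at 4 days, and rest on single DMSO libraries. In WT cells they were positive for Hp (2.55), Kirrel3 (2.12), U90926 (1.95), Prl2c2 (1.61) and Saa3 (1.37). They were negative for Slfn5 (−3.06), Rsad2 (−2.94), Apod (−2.84), Ifi44l (−2.78) and Irf7 (−2.61). In DKO cells they were positive for Pcdhga6 (4.13), Meox2 (3.89), Tmem26 (3.33), Igfbp3 (2.79) and Fibin (2.73). Negative ones there were Sall1 (−8.26), Mest (−7.88), Tet1 (−6.34), Peg3 (−5.5) and Zfp764 (−4.16), and the gap between the 2 DKO DMSO libraries enters all of these DKO values.

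The first pattern is the 2944 genes that were lower in DKO than WT in DMSO and rose under CP1 in DKO cells. WT cells mixed into the DKO CP1 cultures are argued against, since 178 genes near 0 in DKO DMSO recovered a median of 0.614% of their WT DMSO level (quartiles 0.0755% and 2.53%). The pattern's genes, which were chosen for rising under CP1, recovered 57.7% of the WT distance (quartiles 32.5% and 90.8%). Genes that CP1 lowers in WT cells, such as Ifi44l (55.12 to 0.4 CPM), recover less on this scale even if WT cells are present. Hoxd11 and Pdgfd, picked after their values were seen, stood at 33.0 and 38.9 CPM in WT CP1 and at 0 in DKO CP1. Cells with undeleted Lats1 and Lats2 are argued against as well, since the rise of Lats1 would need 22.6% of such cells and a Lats2 rise of 0.52, and Lats2 moved by 0.03 (SE 0.09). A different share of Xist-expressing cells, mixed at 1 ratio, cannot be told apart as the whole cause, with 1 DKO DMSO library per day. In DMSO at 4 days 45.9% of 2943 genes had moved under 0.1 of the way to CP1, but the 0.4 of Xist lay within the quartiles (−0.079 and 0.483). A change of cell makeup in the DKO cultures, and a CP1 effect on these genes, both stay open.

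The second pattern is the fall of interferon-stimulated genes in WT cells under CP1. Macrophages in the WT DMSO cultures are argued against, since Lyz2, Csf1r and Cd68 stood at 0.27, 0.42 and 4.88 CPM in WT DMSO and their median log2 change was −0.09, although the list members Mpeg1 (−5.08) and Cd14 (−1.03) fell. A library batch marked by ribosomal RNA cannot be told apart from the treatment, because the fall of −2.57 in the CP1 library low in ribosomal RNA rests on 1 library. An interferon response of the WT DMSO cultures alone cannot be told apart either, with 1 DMSO library per day. Chi-square per degree of freedom was 1.95 between them, against 2.25 to 5.82 between CP1 repeats. It was 18.64 to 23.94 between WT CP1 libraries of different days, and both DMSO libraries may be from 1 culture. The CP1 medians differed by −1.36 between days, and a CP1 effect on interferon signalling stays open.

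The third pattern is the small share of higher genes on the TPM scale in WT cells under CP1. Ribosomal RNA reads in 3 WT CP1 libraries may account for it, since the share of higher calls went from 7.7% to 68.8% once ribosomal RNA and miRNA genes were removed. No biological explanation of it was tested.

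For CP1 over both genotypes, 1 of 81 splits of the libraries within genotypes called as many genes as the real one, which was the real split itself (6957 genes). The highest other, a split that kept 2 of the real DMSO libraries, called 4471. For genotype under CP1, 1 of 34 splits did, again the real one (10932 genes in a fit of the 8 CP1 libraries, highest other 0). Other labellings of these libraries thus gave fewer calls than the real labels. A further split, which equals the day split, could not be fitted. Both tests take each library as separate, and the labels do not state this, so the splits cannot exclude chance differences between cultures.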

How the results depend on the processing

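Fits without the 3 WT libraries rich in ribosomal RNA and TPM without rRNA and miRNA genes were chosen after the data were seen, and all other settings were planned. Counts of called genes moved by over 1.5 times as follows, and other counts stayed within that. The order in each sentence is genotype in DMSO, CP1 in WT, in DKO, their difference, both genotypes, genotype under CP1, CP1 in WT at 2 and 4 days, in DKO at 2 and 4 days, 4 minus 2 days in WT and DKO, and 4 against 2 days in WT and DKO. At a fold change of at least 2 the counts were 6150, 652, 2546, 2470, 958, 3379, 688, 761, 3232, 1989, 135, 966, 197 and 346, by construction. With limma on log2(TPM + 1) they were 1757 (CP1 in WT), 4580 (both), 936, 1384, 5840, 3929, 81, 558, 386 and 483 (each day and between days, in order). With DESeq2 they were 2344 and 2372 (WT at 2 and 4 days), 285 (4 minus 2 days in WT), 1203 and 2133 (4 against 2 days). CP1 in WT called 5987 genes with 8 group means and 5197 with only the libraries compared, and 4 minus 2 days in WT 1379 with 6 libraries. Without the 3 libraries the counts were 345 (CP1 in WT), 2419 (difference), 2577 (both), 5253 (genotype under CP1) and 2414 (WT at 2 days), with fewer samples. TPM without rRNA and miRNA genes gave 96 (4 minus 2 days in WT) and 1412 (4 against 2 days in WT). Unless construction is named, the cause was not tested.

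With 1 library left out the counts ran from 8814 to 11507 (genotype in DMSO), 1283 to 5256, 7495 to 8864, 5229 to 8323, 5223 to 8412, 7139 to 9979, 2884 to 5233, 3093 to 5168, 8977 to 9345, 7013 to 8615, 307 to 1287, 3875 to 5111, 1172 to 3615 and 2179 to 4430. CP1 in WT moved beyond 1.5 times without any 1 of the 4 DMSO libraries (1428 and 1283 for WT, 5238 and 5256 for DKO). The relation of CP1 and genotype effects was −0.433 and ran from −0.45 to −0.4, with no value without either DKO DMSO library, and was −0.616 with shared libraries and −0.541 over genes called for genotype. Lists passing camera numbered 12, 18, 10 and 10 of 30, and 1, 2, 1 and 1 with an estimated correlation. For YAP/TAZ-TEAD targets (−0.00851) and aryl hydrocarbon receptor targets (−0.0684) the estimated correlation lay below the preset 0.01. The loss of these lists does not come from correlated members. Fry passed 24 for genotype, 19 for CP1 in DKO and 18 for the difference. The difference of CP1 effects reversed on TPM for Tead2 (0.094), Amotl2 (0.216) and Axl (0.144), and for Dpp10 (−0.051) on TPM without rRNA and miRNA genes, and the cause was not tested. Of 1071 values of named genes under the other settings, 993 kept direction and side of the threshold, 55 lost the call, 19 gained it and 4 reversed. Of 1392 with a library left out, 1314 kept both, 59 lost the call and 19 gained it. With the replicate block the counts were 10402 (genotype under CP1), 3159 and 4555 (4 against 2 days in WT and DKO). Deviations of same-numbered repeats correlated at −0.003 in WT and 0.116 in DKO, across 1 pair of days each, so the samples share only a number. Depth limited mainly genes with a few counts, whose ratios are bounds or intervals.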

Other observations

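The test of shared direction between genotype and CP1 effects in WT cells and the values of single libraries were chosen after the results were seen.

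Among list members chosen by the fixed rule, some of them named in the report for another comparison, DKO cells in DMSO had higher levels of the adipogenic regulator Pparg (log2 fold change 3.23), the vascular receptor genes Flt1 (3.08) and Kdr (2.30), the intermediate filament genes Krt7 (4.61) and Nes (2.69) and the chondrogenic regulator Sox9 (2.80), although the adipocyte, endothelial, epithelial, neural and cartilage lists did not pass. Cnn1, a smooth muscle calponin, was lower (−2.61) while Zyx was higher (2.02), and the Hippo scaffold gene Wwc1 (3.15) and the tumour suppressor gene Nf2 (1.73) were higher while Sav1 was lower (−1.42). Under CP1 in DKO cells Wwc1 fell (−1.44, SE 0.10), as did Nes (−1.60), the cyclin gene Ccnd1 (−1.07) and the DNA licensing genes Mcm2 (−0.60) and Mcm7 (−0.71). Egr1 rose in DKO cells (1.52) and fell in WT cells (−1.16), a difference of 2.68 (SE 0.16; edgeR adjusted p = 7.25e-08), and the Wnt feedback gene Nkd1 rose in DKO cells (2.42). Calls used edgeR's threshold on all genes.

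The HOX list did not pass between genotypes (camera adjusted p = 0.997), and these members were picked after their values were seen. Hoxd11 had 0 counts in all 6 DKO libraries, and Hoxd13 stood at 80.5 to 109 CPM in DKO and 233 to 259 in WT libraries, while Hoxa7 was higher in DKO DMSO (3.47) and Hoxa13 lower (−2.23). Pdgfd also had 0 counts in all 6 DKO libraries, and Thy1 stood at 0.17 to 1.23 CPM in DKO CP1 against 119 to 138 in WT libraries. The DKO cells may thus derive from another starting culture or from few founder cells, a hypothesis these data cannot decide, since the labels give no line per genotype. The one related test is that of mixed-in WT cells, where genes near 0 recovered a median of 0.614% of their WT DMSO level.

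Genes changed by CP1 in WT cells moved in the direction of the DKO genotype more often than independent lists would give, which is the other way from DKO cells. With disjoint libraries, the genotype effect at 2 or at 4 days and the CP1 effect at the other day, 1009 and 865 of the genes higher in DKO DMSO rose, where independent lists would share 629.2 and 587.9. Of those lower 1482 and 1409 fell, against 805.8 and 779.8. With the WT DMSO libraries shared, r across genes was 0.368 and the covariance 0.535, against 0.497 and 0.061 in simulations of unchanged groups. With the disjoint libraries r was 0.277 and 0.218. Interferon-stimulated genes, lower in both comparisons, are part of it, and a lowering of these genes unrelated to TEAD stays open, since the WT DMSO cultures, alike at a chi-square per degree of freedom of 1.95, are the reference of both effects.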
